A study of Mus musculus with 6 samples.

How the data were processed

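Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been carried out on mouse CD4 T cells from the spleen of C57BL/6 mice. Per the labels, naive cells were cultured for 5 days under Th1 or Th2 conditions, with 2 days of stimulation through the T cell receptor and CD28 and 3 further days without it. Each cell type gave 3 libraries: a pull-down with a polyclonal antibody to Ezh2, a pull-down with a control antibody, and input DNA. Per the labels' protocols, DNA of 170 to 250 bp was recovered from a gel, amplified by 18 cycles of PCR and sequenced for 36 cycles on an Illumina GAIIx. CASAVA and the genome build mm9 are named in the submitters' processing notes. Settings of the alignment, the read extension and any filter were not given in the sources used here.

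The deposited values are read counts. Each line of a file held 1 genomic interval without a strand and the count of reads that shared it, with no normalization. The main analysis counted each distinct position once, which limits the effect of PCR duplicates. Because the strand was not given, reads of both strands that fell on the same interval could not be told apart, the planned movement of read ends could not be made, and each interval was counted at its midpoint. Chromosomes 1 to 19 and X were used, which held between 99.65% and 99.77% of the positions of a library. The file of the Th2 control antibody ended inside chromosome 17. Of chromosomes 1 to 19 and X, it was used on the 8 that it held whole (3, 4, 5, 6, 7, 9, 12 and X), and its other chromosomes were not analysed here.

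Ezh2-enriched regions were called per 1 kb bin. A one-sided exact binomial test compared the positions of the Ezh2 library with those of the input of the same cell type, given the library totals. Bins with under 10 positions over both libraries were not tested. A bin was called at a Benjamini-Hochberg adjusted p below 0.05 and a fold of at least 2, with 0.5 added to each count, and called bins with a gap of at most 1 bin were merged. The control antibody libraries went through the same steps. There was 1 library per group, so no replicate spread could be measured. The tests and the 95% exact (Clopper-Pearson) intervals cover counting error only, and they compare these libraries, not the cell types.

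The plan, fixed before the data were examined, compared promoters. No gene annotation of mm9 was used here, and coordinates were not converted between builds, so no gene could be placed on the reads. The planned promoter counts, the comparison of Th1 with Th2 at promoters and the gene lists were therefore not made, and regions are given by mm9 coordinates. The gene table at hand follows GRCm38.p6 and served only for the chromosome on which Hox genes lie, where 39 of 39 listed genes matched. For Th1 against Th2, regions were instead called on both Ezh2 libraries together against both inputs together, and those of at least 3 kb were compared by a two-sided exact binomial test. The expected ratio was the median over these regions, which removes a factor common to all of them. A call needed an adjusted p below 0.05 and a ratio of at least 2. A conditional exact test of the Ezh2 and input positions of both cell types, adjusted over all 2902 regions, tested the difference between the folds over input. This definition was chosen after seeing the data, when other definitions had given other counts; all of those counts are in the closing section.

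The planned rule for named regions took the 5 with the highest fold over input in each cell type among those of at least 3 kb, and up to 10 with the largest ratio each way. The 4 widest regions were added after seeing the data. The steps were tested on simulated data with counting error alone. Against input, simulated regions of several bins were placed at above-median depth, and any called bin counted as recovery. Against input, 50 simulated regions were recovered in 0% of cases at 2-fold, 10% at 3-fold, 98% at 5-fold and 100% at 8-fold with the Th1 depth, over 1316331 tested bins with 2 false bins. With the Th2 depth, over 1413729 tested bins, recovery was 2%, 10%, 90% and 100% at those folds. Each fold had 50 simulated regions, far fewer than were called in the real libraries. This makes the adjusted p harder to reach, so recovery in the real libraries may be higher. For Th1 against Th2, over 2902 regions, the rule of at least 2-fold recovered 98% of 50 regions changed 3-fold with 0 false calls. Its recovery was not computed for smaller changes, where most of the calls made here lay.

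Alternatives were 2 kb bins, all deposited reads, the control antibody as background, a fold of at least 4 with an adjusted p below 0.001, and libraries thinned to equal depth (10809666 Ezh2 and 12862628 input positions). Others added after seeing the data were background scaling, in which the totals came from the 10 kb bins below the median of Ezh2 over input, the input of the other cell type, no minimum of positions, and other settings of the Th1 to Th2 comparison. To test for chance, the positions of the equal-depth libraries were split at random into 2 equal parts, 10 times, and regions were called in each part. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.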

Results

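Binding of Ezh2 was examined in mouse Th1 and Th2 cells. Ezh2 is the catalytic subunit of Polycomb repressive complex 2, which methylates histone H3 at silenced genes. Th1 and Th2 cells are the helper T cell types that arise from naive CD4 T cells in the presence of IL-12 or IL-4. The 6 libraries were an Ezh2 pull-down, a control antibody pull-down and an input from each cell type, with 1 library in each group and no replicates.

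The Ezh2 libraries held 10834902 distinct positions from 24387599 reads in Th1 and 14997378 from 30646106 reads in Th2. The inputs held 15626355 positions in Th1 and 12902652 in Th2. The Th1 control antibody library held 9353748 positions, and the part of the Th2 control antibody library that was used held 5053626. Reads per position were 2.25 and 2.04 in the Ezh2 libraries of Th1 and Th2, against 1.30 and 1.77 in their inputs. All regions are given in mm9 coordinates, and the genes in them were not placed.

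The first question was where Ezh2 was enriched over input in each cell type. The widest region was 133 kb when called in Th1 and 140 kb in Th2. When regions were called on both Ezh2 libraries together, the 4 widest lay on chromosomes 15, 11, 2 and 6. The region at 102734001 to 102908000 on chromosome 15 spanned 174 kb, with Ezh2 8.14-fold over input in Th1 (95% interval 7.71 to 8.61) and 12.2-fold in Th2 (11.5 to 13.0). Next was chromosome 11 from 96103001 to 96242000, at 7.06-fold in Th1 (6.61 to 7.54) and 8.25-fold in Th2 (7.72 to 8.83). On chromosome 2, the region from 74482001 to 74606000 stood at 9.02-fold in Th1 (8.42 to 9.69) and 12.2-fold in Th2 (11.4 to 13.2). On chromosome 6, the region from 52153001 to 52245000 stood at 9.60-fold in Th1 (8.91 to 10.4) and 12.0-fold in Th2 (11.1 to 13.0). The Th1 control antibody lay between 0.960-fold and 1.05-fold over input in these 4 regions.

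**Figure D1:**
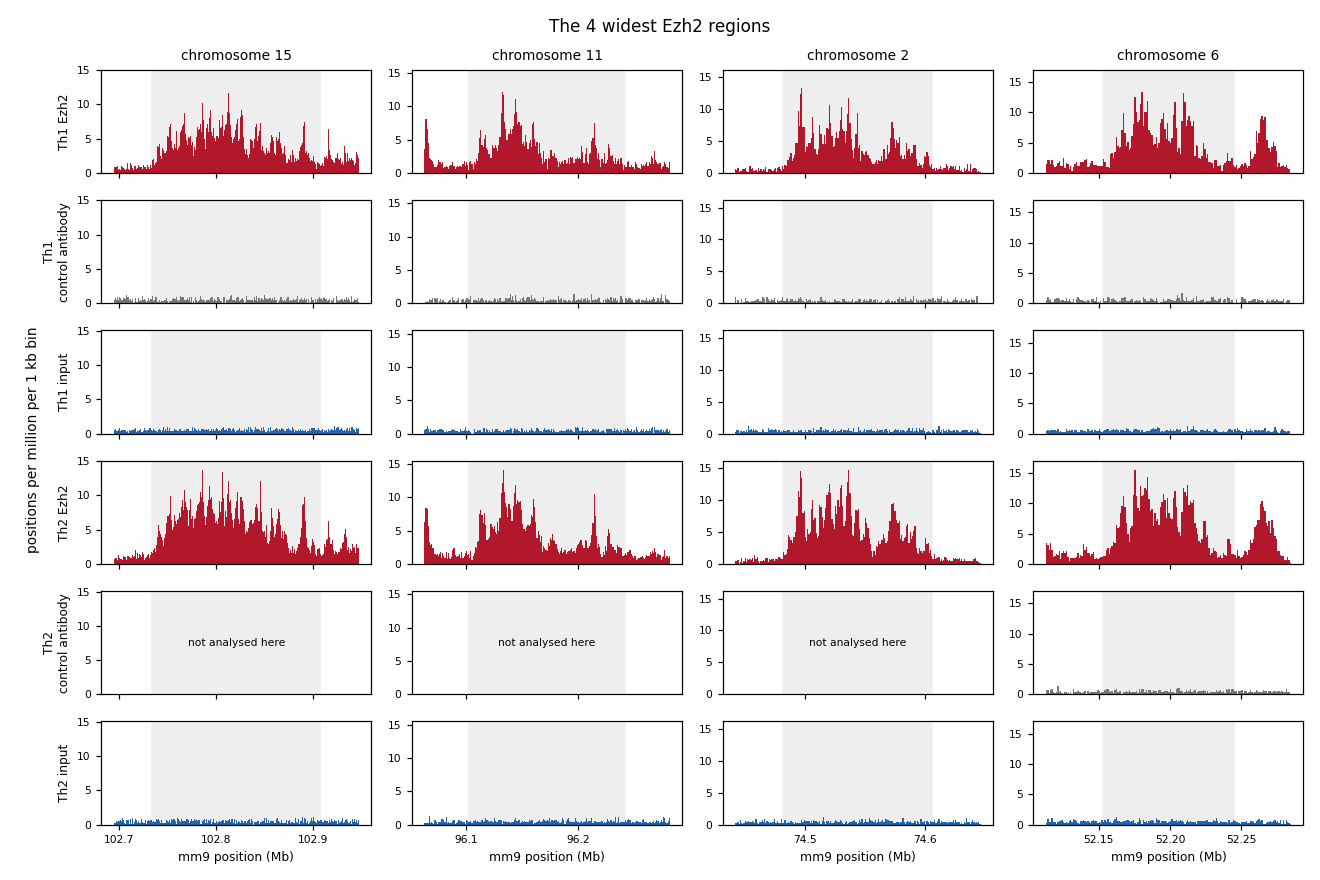
Distinct positions in 1 kb bins, scaled to the library total (vertical axes), along mm9 (horizontal axes, Mb) at the 4 widest Ezh2 regions (shaded). The Th2 control antibody is shown on chromosome 6 alone, since the part of that library used did not cover chromosomes 15, 11 and 2. The total of the partial Th2 control antibody library was extrapolated from the 8 chromosomes used, which held 41.6% of the Th2 input positions. The flanks on chromosomes 15, 11 and 6 hold other called regions. Averaged over a shaded region, the Th1 control antibody was between 0.960-fold and 1.05-fold over input.

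In Th1, 13220 bins were called, which merged into 5664 regions covering 14066 kb. In Th2, 17075 bins merged into 6223 regions covering 18039 kb. The Th1 control antibody gave 20 called bins by the same rule, and thinning the Th1 Ezh2 library to the control depth still left 12579. On 8 chromosomes, the Th2 control antibody gave 0 called bins of 534821 tested, where the Th2 Ezh2 library gave 7062. Most called regions were single bins, 66.3% of them in Th1 and 60.9% in Th2. Regions of at least 3 kb numbered 1445 in Th1 and 1914 in Th2. The numbers of regions depended on the counting: with all deposited reads they were 52902 in Th1 and 84505 in Th2, where the Th1 control antibody also gave 18727, and with background scaling they were 33390 and 26745, where the Th1 control antibody gave 164.

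Among the regions of at least 3 kb called in Th1, whether or not also called in Th2, the fold over input was highest at chromosome X from 133639001 to 133642000 (23.3-fold, 95% interval 8.74 to 134.4). That value rested on 3 input positions, and the control antibody was 4.53-fold over the same input. Of the next 4 in Th1, the region on chromosome 4 from 124333001 to 124340000 had the most positions, 537 in the Ezh2 library, at 15.6-fold (11.8 to 21.6). The others were chromosome 16 from 20589001 to 20593000 at 16.0-fold (9.88 to 29.4), chromosome 14 from 68700001 to 68703000 at 15.0-fold (8.41 to 32.1) and chromosome 12 from 111515001 to 111518000 at 14.8-fold (7.85 to 35.0). The control antibody was 1.87-fold over the same input at the region on chromosome 16, 2.40-fold at that on chromosome 14, with 11 input positions, and 3.43-fold at that on chromosome 12, with 9, but 0.860-fold at that on chromosome 4. Among the regions called in Th2 the highest was chromosome 8 from 94879001 to 94894000 at 23.6-fold (18.5 to 31.2), followed by chromosome 14 from 30532001 to 30536000 at 20.5-fold (8.72 to 85.9), with 4 input positions. Then came chromosome 11 from 85638001 to 85660000 at 18.6-fold (15.7 to 22.4), chromosome X from 138156001 to 138159000 at 18.4-fold (6.00 to 193.0), with 2 input positions, and chromosome 9 from 62982001 to 63002000 at 17.5-fold (14.7 to 21.1).

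The second question was how far the targets were shared. Of the called bins, 8501 were called in both cell types, which was 64.3% of the Th1 bins and 49.8% of the Th2 bins. Independent lists among the 1009392 bins tested in both would share 215. Sharing rose with the length of a region. A part of this is built in, since any bin called in the other cell type counted, and longer regions have more bins. Of the Th1 regions of 10 kb or more, 213 of 213 overlapped a bin called in Th2, and of those in Th2, 316 of 316 overlapped one called in Th1. Of the single-bin regions, 14.8% in Th1 and 7.59% in Th2 did so.

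The third question was which regions differed between the cell types. Calling on both Ezh2 libraries together gave 2902 regions of at least 3 kb, covering 21530 kb. In 2789 of them (96.1%) Ezh2 was at least 2-fold over input in both cell types. Since the regions were chosen for a pooled fold of at least 2 in these same libraries, that share was largely set by the selection. The selection also raises the shares of Ezh2 positions and the median folds given next, and the intervals do not cover it. These regions held 5.07% of the Th1 Ezh2 positions (95% interval 5.05 to 5.08) and 6.14% of the Th2 Ezh2 positions (6.12 to 6.15), against 1.06% and 1.02% of the inputs and 1.03% of the Th1 control antibody positions. The median fold over input was 3.75 in Th1 and 4.52 in Th2, and the fold was higher in Th2 in 2106 regions (72.6%). Across regions, which are not independent replicates, the folds of both cell types had a Spearman correlation of 0.517, which was 0.188 over the 1529 regions of 3 to 5 kb and 0.889 over the 146 of 20 kb or more. Short regions hold fewer positions, so counting error lowers their correlation, and the selection on the pooled fold can lower it too. The value of 0.188 therefore does not measure how far the cell types differ at short regions.

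**Figure D2:**
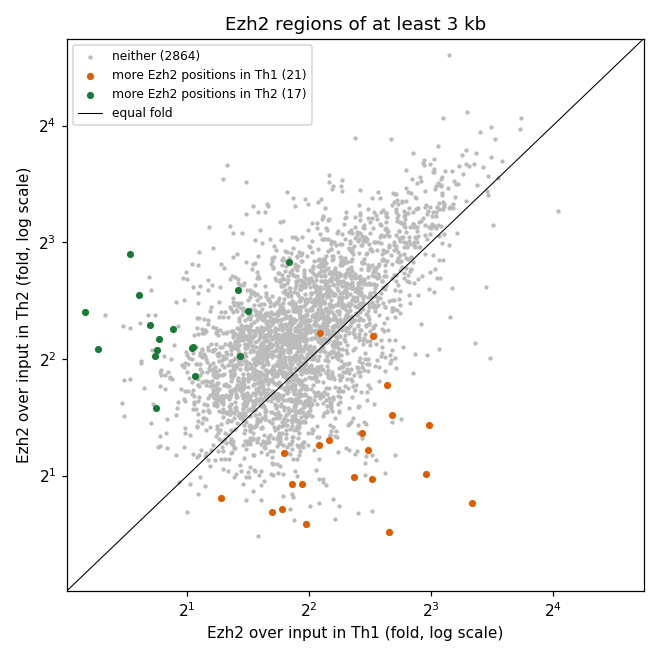
Ezh2 over input in Th1 (horizontal, fold on a log scale) and Th2 (vertical, fold on a log scale) for 2902 regions of at least 3 kb, 1 point each, with the 38 called regions in colour. Most points lie above the line of equal fold, and 21 regions had more positions in Th1 and 17 in Th2 relative to the median ratio.

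Relative to the median ratio, 21 regions had at least 2-fold more Ezh2 positions in Th1 and 17 had at least 2-fold more in Th2, by the two-sided exact binomial test with Benjamini-Hochberg adjustment over 2902 regions. Without the limit of 2-fold, 350 regions passed, 145 higher in Th1 and 205 higher in Th2. With library totals as the expected ratio, the split of the 2-fold calls was 8 and 59. The file names of the Ezh2 libraries carry different run labels, so cell type and sequencing run may not be separable.

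By the same exact test, the largest difference was at chromosome 17 from 87153001 to 87156000, with 143 Ezh2 positions in Th1 and 42 in Th2, a ratio of 5.47 (95% interval 3.89 to 7.98, adjusted p = 6.77e-24). Over input, Ezh2 was 10.1-fold there in Th1 (6.43 to 17.4) and 1.70-fold in Th2 (0.995 to 3.06). At chromosome 15 from 88966001 to 88972000 the counts were 188 and 102, a ratio of 2.98 (2.34 to 3.84, exact test, adjusted p = 2.51e-17). The region on chromosome 11 from 57479001 to 57482000 had a ratio of 3.21 (2.01 to 5.35), with a control antibody 2.07-fold over input. Of the 21 regions higher in Th1, 20 were 3 to 5 kb long, and the rest of the 10 largest ratios lay between 2.29 and 2.75.

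Higher in Th2, the region with the most positions was chromosome 12 from 80531001 to 80544000, with 125 in Th1 and 432 in Th2, 2.13-fold more in Th2 (95% interval 1.74 to 2.62, exact test, adjusted p = 5.53e-13). At chromosome 6 from 99466001 to 99473000 the counts were 64 and 264, 2.53-fold more in Th2 (1.93 to 3.40, exact test, adjusted p = 5.63e-11). At chromosome 18 from 79304001 to 79310000 they were 59 and 219, 2.28-fold more (1.71 to 3.11, exact test, adjusted p = 1.52e-07). The largest ratio was at chromosome 11 from 95799001 to 95802000, 2.74-fold more in Th2 (1.57 to 5.45), on 14 and 64 positions. There the Th1 control antibody was 2.07-fold over input, and the difference in Ezh2 over input was 1.48-fold (exact test, adjusted p = 0.971). The 10 largest ratios lay between 2.21 and 2.74. When the input positions entered an exact test as well, adjusted over all 2902 regions, 4 of the 38 differences passed, those on chromosome 17 from 87153001, chromosome 15 from 88966001, chromosome 12 from 80531001 and chromosome 19 from 30622001. On chromosome 19 the inputs themselves differed, with 34 positions in Th1 and 13 in Th2.

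**Figure D3:**
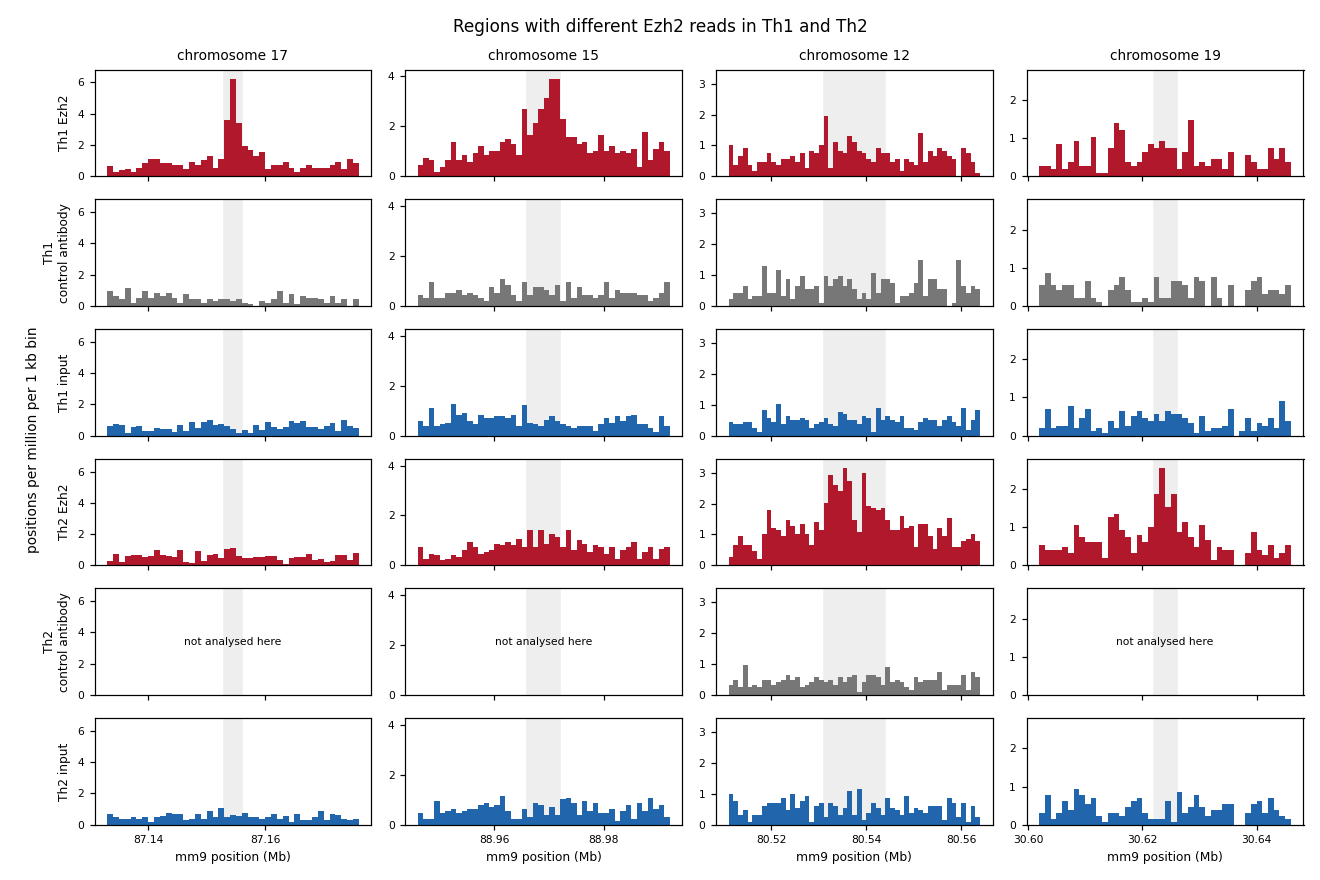
Distinct positions in 1 kb bins, scaled to the library total (vertical axes), along mm9 (horizontal axes, Mb) at 2 regions with more Ezh2 positions in Th1 (chromosomes 17 and 15) and 2 with more in Th2 (chromosomes 12 and 19), shaded. The Th2 control antibody is shown on chromosome 12 alone, since the part of that library used did not cover the others. The Ezh2 positions in the shaded regions were 143 in Th1 and 42 in Th2 on chromosome 17, and 125 and 432 on chromosome 12.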

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

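The tests of the surrounding bins by calls kept and of equal depth were set out before their results were seen. That of low input counts was set out before its own result, but after the 2.04-fold given below was seen, and that of a chance excess over both cell types before its own result, in place of a test that the choice of the regions had decided. The tests of the inputs, of counting error, of a chance excess in each cell type, of pull-down efficiency and of the surrounding sequence as the whole cause were chosen after, as were the definition of the regions and the exact test of the folds, which replaced an approximate test that 7 of the 38 regions had passed.

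Of the 38 regions with different Ezh2 positions, 4 also differed between the Th1 and Th2 libraries in Ezh2 over input, by a conditional exact test adjusted over 2902 regions. The fold in Th1 relative to Th2, after division by the median, was 7.19 at chromosome 17 from 87153001 (exact test, adjusted p = 2.25e-04) and 3.16 at chromosome 15 from 88966001 (exact test, adjusted p = 0.00253). It was 0.233 at chromosome 19 from 30622001 and 0.497 at chromosome 12 from 80531001 (exact test, adjusted p = 0.0294 for each). On chromosome 19 the inputs held 34 positions in Th1 and 13 in Th2, and the Ezh2 positions alone gave a ratio of 0.476. With all deposited reads that ratio was 0.573, and after correction for the surrounding bins it was 0.555 there and 0.505 on chromosome 12, each short of 2-fold. For the other 34 the test of the folds did not pass. In 22 of them the difference stayed at 2-fold or more once the inputs entered (between 2.05 and 3.21 before, 2.07 and 5.31 after), while the median counting error on the log2 scale went from 0.307 to 0.557. In 12 it fell short of 2-fold (between 2.04 and 2.74 before, 1.11 and 1.86 after), with an error of 0.311 before and 0.583 after.

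Counting error does not account for the 38 differences: 100 simulations without a difference gave at most 1 call. The simulations held counting error only, as the exact test assumes, so they repeat that test and do not cover spread between libraries. A difference between the inputs is argued against only for the 38 regions pooled. Their median input difference in the same direction was 0.0107 of the Ezh2 difference on the log2 scale. That median joins both directions. Of the 12 regions that fell short of 2-fold, 4 were higher in Th1 and 8 in Th2. An input-corrected ratio of at least 2 was kept by 17 of the 21 regions higher in Th1, but by 9 of the 17 higher in Th2. A part of the inputs therefore stays open for the regions higher in Th2. It also stays open for single regions such as chromosome 14 from 31943001, with 23 input positions in Th1 and 9 in Th2. There the ratio fell from 2.19 to 1.11 once the inputs entered. On chromosome 19 from 30622001 the inputs differed the opposite way to the Ezh2 positions. The Th1 to Th2 ratio of uncalled bins within 500 kb covered a median of 0.0781 of the log2 difference, and at most 0.312. Over the 2902 regions that ratio had a standard deviation of only 0.0917 on the log2 scale. The calls were picked for at least 2-fold, so a small share was near certain. A bias spread evenly over those bins was too small to be the whole cause, but a narrower one is not covered. After division by the surrounding ratio 23 of 38 calls remained, and the folds of the other 15 went from between 2.04 and 2.38 to between 1.66 and 2.02, so a part in these is open. A difference between the cell types was not separable from one between sequencing runs, with 1 library each, and a bias of the regions' own sequence was not tested.

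Ezh2 over input was higher in Th2 in 72.6% of the regions of at least 3 kb. The Th2 input is argued against, since with the Th1 input for both cell types the share was 76.8%. At equal depth the share was 72.0%. The folds are already scaled by the library totals, and thinning leaves such folds unchanged on average. That test could therefore hardly have pointed to depth, and no conclusion is drawn from it. Unequal pull-down efficiency and a difference between the cell types cannot be told apart, because each could shift most regions the same way. The median Th1 to Th2 ratio was 0.854 after division by the library totals. The shift was not 1 factor for all regions. Relative to that median, the ratio had a median of 1.03 over regions of 3 to 5 kb and 0.948 over those of 20 kb or more. Division by 1 median therefore leaves a slight tilt toward Th1 in short regions and toward Th2 in long ones.

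Most single-bin regions were called in 1 cell type only. With the libraries split at random into 2 parts of equal depth, 17.8% of the Th1 single-bin regions of a part were called in the other Th1 part and 24.6% in a Th2 part, a ratio of 1.37 (1.30 to 1.45 over 10 splits), above the bound of 0.8 for a chance excess of positions. Of the Th2 ones 16.7% were called in the other Th2 part and 7.75% in a Th1 part, a ratio of 0.474 (0.423 to 0.509) that lay across the lower bound of 0.5. Ezh2 over input was higher in Th2 in most longer regions. Stronger enrichment in Th2 would raise the Th1 ratio and lower the Th2 one, with or without chance. The splits therefore do not decide on chance, which stays open as the cause in both cell types. Over both cell types the ratio was 0.886, which met the bound of 0.8 set beforehand for chance but hides these opposite directions. In the Th1 ones not called in Th2 at full depth the control antibody was 2.04-fold over the same input, but 0.955-fold over the Th2 input, and these bins had a median of 4 Th1 input positions against 8 in all tested bins. Low input counts in the bins selected fit these values.

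Outside chromosomes 1 to 19 and X, sequences the comparisons did not use held 6 called of 1304 bins tested in the Th1 Ezh2 library (0.460%) and 9 of 1354 in the Th2 one (0.665%), where the Th1 control antibody gave 0 of 1282. On the chromosomes used, 13220 of 1332288 were called in Th1.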

How the results depend on the processing

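Alternatives other than 2 kb bins, all reads, strict thresholds, equal depth and the control antibody as background were chosen after seeing the data, as were all of those for regions of at least 3 kb, shared bins and Th1 against Th2. No paired analysis was possible because each group had 1 library. The alternatives for promoters, gene lists and named genes, and the movement of read ends, were not run, since genes were not placed and strands not given. The cause of each change below was not tested, except where stated.

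The numbers of enriched regions stayed within 1.5 times with 2 kb bins, equal depth, no minimum, the input of the other cell type and the control antibody as background (Th2 on 8 chromosomes), except that 2 kb bins gave 2193 Th1 regions of at least 3 kb. All deposited reads gave 52902 regions in Th1 and 84505 in Th2, with 4812 and 8833 of at least 3 kb and 18987 shared bins. Background scaling gave 33390 and 26745, with 4371 and 4338 of at least 3 kb. A fold of at least 4 with an adjusted p below 0.001 gave 1951 and 2422, with 759 and 1112 of at least 3 kb and 5138 shared bins, by its own construction fewer.

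For Th1 against Th2 (21 and 17 as reported), regions called in either cell type separately, the definition tried first, gave 850 higher in Th1 and 157 in Th2, regions of every length gave 77 and 68, and these with the expected ratio from those of at least 3 kb gave 110 and 26. Library totals gave 8 and 59, and the strict thresholds 1 and 0. All deposited reads gave 28 and 26, equal depth 24 and 18, an input-corrected ratio of at least 2 gave 17 and 9, and correction for surrounding bins 16 and 8. Of the 38 called regions, none reversed with all reads, equal depth or that correction, and 6, 5 and 15 no longer passed. Their folds, from 2.04 to 2.38 as reported, were then between 1.54 and 1.91 with all reads, 1.85 and 2.08 at equal depth, and 1.66 and 2.02 after the correction. With all reads the 6 were lost by the 2-fold limit alone, while 1 at equal depth and 3 after the correction missed the adjusted p. Library totals multiply every ratio by 1 factor, so no reversal could arise, and 13 regions then fell short of 2-fold, at 1.74 to 1.99. All reads, equal depth and the correction reuse the same libraries. A reversal of a 2-fold difference was unlikely there too, so its absence is no check of direction. Weak enrichment was mostly missed in the simulations: at 3-fold over input, 10% of simulated regions were recovered in either cell type. The simulations held 50 regions at each fold, far fewer than were called here. With fewer regions the adjusted p is harder to reach, so recovery in the real libraries may be higher. Neither the depth nor the number of regions was varied, so the missed regions are not put down to depth.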

Other observations

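The tests here were chosen after the patterns were seen. Chromosome 11 had the most sequence in regions of at least 3 kb, 18.7 kb per Mb, followed by chromosome 19 with 15.0. Chromosome X had 0.936 kb per Mb, and the autosomes at least 4.65. The input depth of X was 2.40 positions per kb in Th1, where autosomes had at least 5.52. The regions on X had a median fold over input of 5.71 in Th1 and 7.16 in Th2. At a lower depth a bin needs a higher fold to be called. The few regions on X and their high folds may therefore follow from the depth, which was not tested.

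A hypothesis was that the windows with the most Ezh2-called sequence lie on the 4 chromosomes that carry Hox clusters (2, 6, 11 and 15). Hox genes are developmental genes known as Polycomb targets. As stated, with the 4 windows of 200 kb that held the most called sequence, it failed. Of these windows, 3 lay on different Hox chromosomes (15, 11 and 6) and the other on chromosome 19, with 128 kb called. Chromosome 2 came next with 124 kb, the whole of its span, at 9.02-fold over input in Th1 and 12.2-fold in Th2. The window on chromosome 19 stood at 4.19-fold in Th1 and 5.26-fold in Th2. The ranking was thus by length called, not by fold. Random draws of 4 chromosomes, weighted by their number of regions, gave 3 or more Hox chromosomes in 2.86% of 100000. Ranking single regions by width instead put the 4 widest on the 4 Hox chromosomes, which 0.056% of draws gave. That ranking is the one in which the pattern was first noticed, so it is not independent evidence, and whether the regions hold Hox genes was not tested here.

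A second hypothesis was that regions higher in Th2 lie near each other, from several on chromosome 6 between 99190001 and 99473000. It was not borne out. Of 205 regions with an adjusted p below 0.05, 40 had another within 500 kb, where random draws of as many regions gave a median of 44 (one-sided permutation p = 0.722, 1000 draws). For the 145 regions higher in Th1 the number was 32 against a median of 23 (one-sided permutation p = 0.0949).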
